A study of Rattus norvegicus with 16 samples.

How the data were processed

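Per the labels' growth and treatment protocols, RNA came from primary cultures of hippocampal neurons of embryonic day 18 Sprague-Dawley rats, while the extraction protocol names hippocampal tissue as its source. It was measured on 1-colour (Cy3) Agilent rat gene expression arrays. Per the labels, cultures were treated with 5 µM hydroxyurea for 2, 6, 12 or 24 h or left untreated, with 3 replicates of each of the 5 groups, 15 samples in all. The samples took 16 arrays on 2 slides, because untreated replicate 1 was hybridised on both slides; its 2 arrays were averaged on the log2 scale and counted as 1 sample. Slide 1 held untreated replicate 2, 2 h replicates 1 and 2, 6 h replicates 1 and 2, 12 h replicate 1, 24 h replicate 3 and the first array of untreated replicate 1, and slide 2 held the rest. Per the labels' protocols, neurons grew in Neurobasal medium with 5% B27, which was replaced by medium with B27 lacking antioxidants before hydroxyurea was added, and 200 ng of RNA was labelled per array. The labels give the age of the cultures as 6 to 9 days in one field and as at most 8 days in another, and they do not say how long the untreated cultures spent in the new medium, so the untreated group is not known to be matched in time to any treated group. Replicates are numbered 1 to 3 in the sample titles and the design and lettered A to C in the treatment protocol, and nothing in the labels says that they were separate cultures.

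Per the file headers, the deposited scanner files hold spot intensity from Agilent Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12; the processed signal is an intensity from which background was subtracted, with a substitute value where a spot was not above background, and it was not scaled between arrays. The headers name rat build rn4 for the design, and no coordinates were used. The series values, as deposited by the authors, are a standard score per array, which was checked against the scanner files to be the log of the processed signal of an array less its mean, divided by its SD over all spots and rounded to 2 decimals. Its correlation with the array's own scanner file was 0.999996, with a largest difference of 0.00502. The columns of 24 h replicates 1 and 3 matched each other's scanner file instead (0.999996, against 0.991 with their own). Column medians of this score ranged from -0.03 to 0.03. The scanner files were used as labelled, and these scores were an alternative. What steps, if any, followed this score in the study is not given in the sources used here.

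Each array had 62976 spots. The 4259 control spots were left out, and the remaining 58717 spots hold 30367 distinct probes. Spots with an outlier flag were left out, which left 75 probes without a usable spot on at least 1 array, and spots of a probe were averaged. Probe accessions were matched without versions to a table of RefSeq genes: 18758 probes matched 15715 symbols, and 11609 probes, mostly Ensembl transcripts and other records outside that table, stayed unnamed and were tested by probe. A probe counted as well above background on an array if most of its spots did. The value tested was log2 of the processed signal minus the 75th percentile of log2 values over the non-control probes of the array. For a gene with several probes the one with the highest mean over all samples was used, and a probe was kept if well above background on every array of at least 1 group. This left 18241 features, 11146 named genes and 7095 unnamed probes. A group in which a probe was on no array well above background has only a bound, computed from the mean of the brighter group against, per array, the higher of the probe's own value and the lowest signal well above background. The bound is a difference of means and carries no sampling error. Such a probe was kept through another group in which it was brighter.

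Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 fit over all 15 samples with 10 residual and 3.51 prior degrees of freedom, two-sided, with no covariate), with version 1.17.8 of data.table. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Comparisons were each treatment time with untreated, the mean of the 4 times with untreated, 24 h with 2 h, and a moderated F test among the 4 times. The 36 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists; camera with an estimated correlation and fry, which asks whether a list itself moves one way, were run beside it. A list's shift is the mean log2 difference of its measured members. For the 3 genes followed in every sample and for the mean deviation of each list per sample, treated samples were set against untreated ones by an exact permutation test over all 455 splits of the 15 samples into 12 and 3. A test of 3 against 3 samples has 10 splits and cannot give an exact p below 0.1.

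The lists were ribonucleotide reductase and deoxynucleotide supply, p53 targets, replication checkpoint and DNA repair, cell cycle, NRF2 and antioxidant genes, immediate early genes, the integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, HIF and glycolysis genes, the nuclear-encoded respiratory chain, cholesterol synthesis, lysosome and autophagy, apoptosis regulators, glutamate receptors and the postsynaptic density, presynaptic release, GABA receptors with calcium and potassium channels, neurotrophins and growth factors, nitric oxide and cyclic GMP signalling, Alzheimer disease and amyloid genes, inflammatory genes, interferon-stimulated genes, the circadian clock, glucocorticoid and thyroid responsive genes, globin and erythroid genes, iron handling, Wnt and Notch genes, ribosomal proteins, and markers of neurons, GABAergic interneurons, astrocytes, radial glia, oligodendrocytes, microglia, endothelium and meningeal fibroblasts or pericytes.

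The genes named were fixed by a rule before the data were examined: in each comparison with untreated, up to 8 genes per direction past the threshold with separated values, and where fewer passed, those with the smallest unadjusted p up to 5 per direction, named as not passing, only where the gene has a symbol; the subunits of ribonucleotide reductase (Rrm1, Rrm2, Rrm2b) were to be named whatever their values. Members of lists given as examples were chosen after their values were seen. The gene test was tried on simulated values, drawn independently for each feature, in which 200 of the 18241 features were changed by known folds. The steps before the gene test and the permutation tests were not simulated, and no shift of a list was planted. At the spread of these samples, 76%, 60%, 78% and 78% of features changed 2-fold were recovered at 2, 6, 12 and 24 h, and 96%, 96%, 96% and 94% of those changed 4-fold. For the mean of the 4 times the shares were 86% and 98%. Of features changed 1.5-fold only 30%, 30%, 36% and 32% were recovered at 2, 6, 12 and 24 h, and 48% in the mean. Changes of 1.5-fold to 8-fold were planted together, so these shares need not hold for a feature that changes alone. Between 4 and 13 of the calls in each of these simulated comparisons were false.

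Alternatives were other scalings (quantile, median, Z-score), normexp background correction with an offset of 50, other filters and probe rules, array weights, a trended and robust fit, the slide and the replicate number as blocks, single slides, other choices of the repeated arrays, each replicate left out, and other thresholds. Normexp was run on the median signal because the scanner files hold no mean signal. All spots entered the normexp fit and control spots were left out after it. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. For arrays the number of samples limits the precision; the median standard error of a log2 difference was 0.16 for 1 time and 0.13 for the mean of the 4 times.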

Results

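Gene expression was measured in cultured rat hippocampal neurons left untreated or treated for 2, 6, 12 or 24 h with hydroxyurea (5 µM), an inhibitor of ribonucleotide reductase, the enzyme that makes deoxynucleotides. The study concerns whether the drug shields such neurons from several kinds of stress. The comparisons address which transcripts differed during treatment. Each of the 5 groups had 3 samples. Between 64.7% and 70.4% of probes were well above background on each of the 16 arrays, and no spot was saturated. Replicate spots differed by a median coefficient of variation of 3.38% to 7.34% on 14 arrays, by 15.5% on the first array of untreated replicate 1 and by 23.1% on the array of 12 h replicate 3. The first principal component, 29.6% of the variance, set 12 h replicate 3 apart from the other samples. P-values here measure only the spread between these samples, which may be technical, because nothing says that replicates came from separate cultures.

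**Figure D1:**
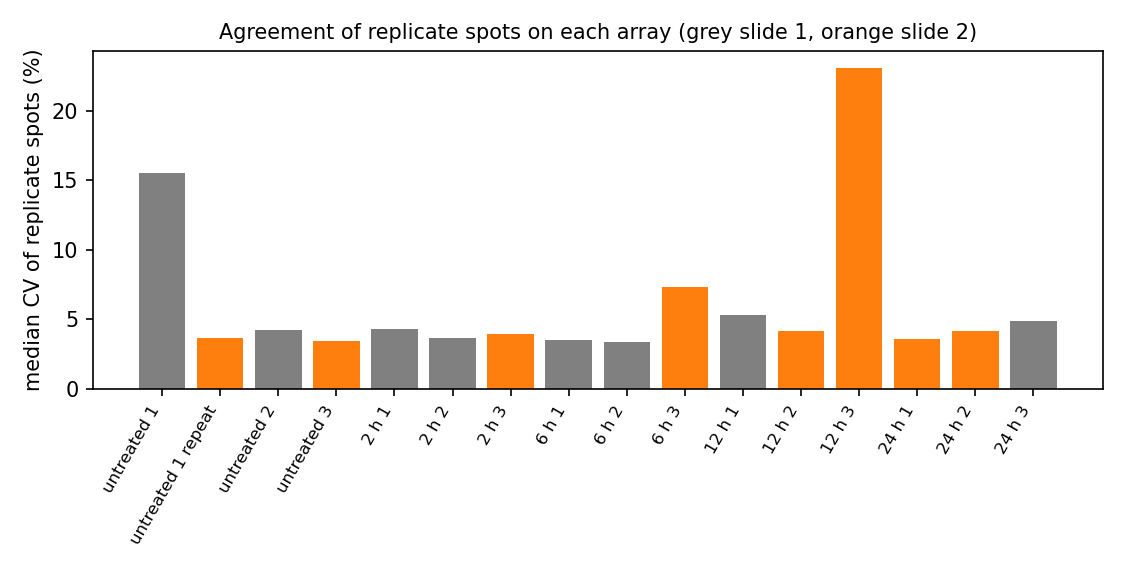
Median coefficient of variation (in percent) of replicate spots of the same probe on each of the 16 arrays, grouped by treatment, with slide 1 in grey and slide 2 in orange. The first array of untreated replicate 1 (15.5%) and the array of 12 h replicate 3 (23.1%) stand above the other 14.

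The genes of the target enzyme were near their untreated level at every time. Rrm1 (NM_001013236), the large subunit, had a normalised log2 signal of -4.18 ± 0.08 (SD, n = 3) in untreated and -4.14 ± 0.17 (SD, n = 12) in treated samples, a difference smaller than the spread between replicates (exact permutation p = 0.666, two-sided). Rrm2 (NM_001025740), the small subunit that limits the enzyme in dividing cells, was at 3.01 ± 0.21 (SD, n = 3) in untreated and 3.13 ± 0.21 (SD, n = 12) in treated samples (exact permutation p = 0.387). The log2 differences of Rrm1 at 2, 6, 12 and 24 h were 0.03, 0.03, 0.17 and -0.08 (SE 0.13 each), and those of Rrm2 were 0.20, 0.15, 0.16 and -0.01 (SE 0.17 each). The other probe of Rrm2 gave 0.05, 0.12, 0.32 and -0.06. Its mean level over all samples was -3.42, against 3.11 for the probe tested. Which of the 2 probes reflects the level of Rrm2 was not tested, so the levels above are those of 1 probe. The 1 probe of Rrm2b, the subunit used outside S phase, was well above background in 0 samples and was not tested. With the slide as a block the mean differences were 0.04 for Rrm1 and 0.12 for Rrm2; within slide 1 they were -0.02 and -0.00, and within slide 2 they were 0.15 and 0.19. Under a Z-score scaling the sign of Rrm1 turned at 2 h, at 6 h and in the mean of the 4 times, and that of Rrm2 turned at 24 h.

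At 2 h of hydroxyurea, the earliest time, the genes for ribosomal proteins were higher as a group. They encode the structural parts of the cytosolic ribosome. No single gene passed the test. Of 41 measured ribosomal protein genes, 40 had a higher mean in treated than in untreated samples, with a mean shift of 0.13 on the log2 scale (limma's camera, adjusted p = 1.81e-07). The call was lost when the correlation between members, estimated at 0.491, was used (adjusted p = 0.802 with an estimated correlation). Rpl14 stood at 0.25 (SE 0.17), Rps16 at 0.16 (SE 0.11) and Rps15 at 1.03 (SE 0.53). Of the members 0 passed over all genes or adjusted over the list alone. None of the genes with the smallest unadjusted p passed. Among them the receptor of urokinase Plaur had a log2 difference of 1.03 (SE 0.23) and the protease Prss30 one of 0.85 (SE 0.24). Next came the olfactory receptor gene Or52b2 with 0.45 (SE 0.12) and the hypoxia-responsive gene Ankrd37 (NM_001108400) with 0.65 (SE 0.20). On the other side were the vesicular monoamine transporter Slc18a2 (-0.53, SE 0.18; -0.28 without 2 h replicate 3), the complement regulator Cd55 (-0.62, SE 0.18) and the hyaluronan-binding protein gene Tnfaip6 (-0.39, SE 0.13). The aldo-keto reductase Akr1b8 (-0.67, SE 0.18) and Zc3h12b (-1.03, SE 0.30) were not well above background in any 2 h sample. Their differences have only a bound, 1.40-fold and 1.18-fold lower, which carries no sampling error. Normexp background correction turned Akr1b8 to 0.01 and did not turn the sign of Zc3h12b. Plaur was well above background in 1 of 3 untreated samples.

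Of 18241 features tested with limma at 2 h, 0 passed an adjusted p of 0.05 (smallest 1.00), and 220 had an unadjusted p under 0.05, 123 higher and 97 lower, where 912 are expected by chance. In 1158 features (6.35%) the 3 treated values lay on 1 side of the 3 untreated values, where chance gives 10%. Both chance figures, here and at the other times, assume samples that vary independently, which does not hold if same-numbered samples vary together. The other 35 lists did not pass. The ribosomal shift was 0.14 with the slide as a block (adjusted p = 4.29e-08), 0.07 within slide 1 (adjusted p = 0.813) and 0.25 within slide 2 (adjusted p = 4.04e-08), where the 1 sample of 2 h is assumed to vary like the other groups. After quantile normalization it was 0.04 (adjusted p = 0.385).

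At 6 h, genes induced by the hypoxia-inducible factors together with genes of glycolysis were higher as a group, and so were markers of astrocytes, the glia that support neurons. Of 33 measured HIF and glycolysis genes 21 had a higher and 12 a lower mean in treated samples, with a mean shift of 0.10 (limma's camera, adjusted p = 0.00376; adjusted p = 0.388 with an estimated correlation). Of 20 astrocyte markers 15 were higher and 5 lower, with a mean shift of 0.09 (adjusted p = 0.0473; adjusted p = 0.715 with an estimated correlation). Ankrd37 stood at 0.69 (SE 0.20) and the glycolytic enzyme Aldoc, a member of both lists, at 0.40 (SE 0.18). In either list 0 members passed over all genes or adjusted over the list alone. Genes with the smallest unadjusted p that did not pass were, besides Ankrd37, the ferroptosis suppressor Aifm2 (0.77, SE 0.29; 0.29 without untreated replicate 1), Atosb (0.44, SE 0.17), the homeobox factor Pbx2 (0.36, SE 0.13) and the actin regulator Whamm (0.33, SE 0.12). Lower means were seen for Zc3h12b (-1.24, SE 0.30, with a bound of 1.15-fold), the anaphase-promoting complex subunit Cdc27 (-0.86, SE 0.25, and -0.53 without 6 h replicate 3), the transcription factor Atf7 (-0.75, SE 0.21), the membrane progestin receptor Paqr5 (-0.74, SE 0.19) and the orphan nuclear receptor Nr0b1 (-0.34, SE 0.11). Under normexp background correction Zc3h12b stood at 0.03, so its bound did not hold there. The second probe of Aifm2 gave 0.05.

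With limma 0 of 18241 features passed at 6 h (smallest adjusted p 1.00), and 136 had an unadjusted p under 0.05, 75 higher and 61 lower. Values separated the groups for 698 features (3.83%, against 10% by chance). The HIF shift was 0.10 with the slide as a block (adjusted p = 2.73e-04), 0.14 within slide 1 (adjusted p = 0.0129) and 0.09 within slide 2 (adjusted p = 0.456), and without untreated replicate 2 it was 0.11 (adjusted p = 0.106). The astrocyte list passed in 12 of 36 settings. Its shift was 0.04 without untreated replicate 3 (adjusted p = 0.990), 0.08 with the slide as a block (adjusted p = 0.0656), 0.11 within slide 1 (adjusted p = 0.970) and 0.05 within slide 2 (adjusted p = 0.972), where the 1 sample of 6 h is assumed to vary like the other groups.

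At 12 h the groups that were higher were ribosomal protein genes, astrocyte markers and HIF and glycolysis genes. Of 41 ribosomal protein genes 37 had a higher mean, with a mean shift of 0.14 (limma's camera, adjusted p = 2.60e-04; adjusted p = 0.957 with an estimated correlation). Of 20 astrocyte markers 17 were higher, with a mean shift of 0.16 (adjusted p = 0.0151; adjusted p = 0.691 with an estimated correlation), and of 33 HIF and glycolysis genes 24 were higher, with a mean shift of 0.12 (adjusted p = 0.0370; adjusted p = 0.691 with an estimated correlation). Aldoc stood at 0.54 (SE 0.18), the astrocytic glutamate transporter Slc1a2 at 0.46 (SE 0.18), the lactate transporter Slc16a3 at 0.44 (SE 0.17), the angiogenic factor Vegfa at 0.41 (SE 0.15) and Rps19 at 0.38 (SE 0.17). In the 3 lists 0 members passed over all genes or adjusted over the list alone. The genes with the smallest unadjusted p, none past the threshold, were the phosphatidate phosphatase Lpin1 (0.73, SE 0.19), the lipid kinase Pi4k2b (0.75, SE 0.20), Ankrd37 (0.73, SE 0.20), the olfactory receptor gene Or11m3 (0.51, SE 0.14) and the channel gene Calhm2 (0.40, SE 0.11). With lower means were the small RNA methyltransferase Henmt1 (-1.05, SE 0.24), gamma-glutamyl transferase Ggt1 (-0.70, SE 0.20, and -0.42 without 12 h replicate 3), Cd55 (-0.65, SE 0.18, with a bound of 1.5-fold), tropomodulin Tmod1 (-0.61, SE 0.16, and -0.38 without 12 h replicate 1) and the G protein subunit Gnal (-0.43, SE 0.13, and -0.28 without 12 h replicate 3). Under normexp background correction Cd55 stood at 0.14, so its bound did not hold there.

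With limma 0 of 18241 features passed at 12 h; 422 had an unadjusted p under 0.05, 241 higher and 181 lower, and the smallest adjusted p, 0.325, belonged to an unnamed probe. Values separated the groups for 921 features (5.05%, against 10% by chance). With the slide as a block the ribosomal shift was 0.14 (adjusted p = 0.00224), the astrocyte shift 0.16 (adjusted p = 0.00696) and the HIF shift 0.12 (adjusted p = 0.0937). Within slide 1, where the 1 sample of 12 h is assumed to vary like the other groups, they were 0.07 (adjusted p = 0.995, with the test pointing down), 0.13 (adjusted p = 0.995) and 0.14 (adjusted p = 0.662). Within slide 2 they were 0.20 (adjusted p = 2.41e-06), 0.16 (adjusted p = 0.110) and 0.12 (adjusted p = 0.123). Without untreated replicate 3 none of the 3 lists passed, with adjusted p of 0.0954, 0.394 and 0.0637 in that order, and without 12 h replicate 3 the ribosomal shift was 0.09 (adjusted p = 0.0226) and 9 lists passed, 5 up and 4 down. After quantile normalization none passed either, with adjusted p of 0.918, 0.0850 and 0.0989.

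At 24 h, the longest exposure, HIF and glycolysis genes were higher as a group. Genes for GABA receptors and calcium and potassium channels, which set neuronal excitability, were lower as a group. Both calls held with an estimated correlation and were lost with fry (adjusted p = 0.192 and 0.477). Of 33 HIF and glycolysis genes 29 were higher, with a mean shift of 0.15 (limma's camera, adjusted p = 3.71e-06; adjusted p = 0.0399 with an estimated correlation). Of 32 receptor and channel genes 27 were lower, with a mean shift of -0.11 (adjusted p = 5.21e-06; adjusted p = 0.0399 with an estimated correlation). Among HIF and glycolysis members Ankrd37 stood at 0.73 (SE 0.20), Pgk1 at 0.68 (SE 0.34), Slc16a3 at 0.51 (SE 0.17) and Aldoc at 0.41 (SE 0.18). Among channel members the potassium channel gene Kcnj6 stood at -0.34 (SE 0.15), the GABA receptor subunit Gabrb2 at -0.29 (SE 0.21) and the calcium channel subunit Cacnb4 at -0.24 (SE 0.17). In both lists 0 members passed over all genes or adjusted over the list alone.

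Other lists passed the preset test at 24 h and not the one with an estimated correlation. Astrocyte markers were higher, 18 of 20, with a mean shift of 0.13 (limma's camera, adjusted p = 0.00143; adjusted p = 0.154 with an estimated correlation), with Slc1a2 at 0.33 (SE 0.18). Ribosomal protein genes were higher, 35 of 41, with a mean shift of 0.09 (adjusted p = 0.00198; adjusted p = 0.734 with an estimated correlation). Genes of glutamate receptors and the postsynaptic density were lower, 28 of 37, with a mean shift of -0.04 (adjusted p = 0.00570; adjusted p = 0.193 with an estimated correlation), with the synaptic adhesion genes Lrrtm2 at -0.31 (SE 0.18) and Nlgn1 at -0.20 (SE 0.11). Genes of presynaptic release were lower, 20 of 29, with a mean shift of -0.06 (adjusted p = 0.0118; adjusted p = 0.454 with an estimated correlation), with the fusion protein gene Snap25 at -0.19 (SE 0.14), and did not pass under the Z-score (adjusted p = 0.0876) or with the deposited scores (adjusted p = 0.127). Cell cycle genes were lower, 30 of 43, with a mean shift of -0.04 (adjusted p = 0.00570; adjusted p = 0.261 with an estimated correlation), with the spindle gene Tpx2 at -0.29 (SE 0.12). Neuron markers had a mean shift of -0.04, 13 of 19 lower (adjusted p = 0.142), and those of GABAergic interneurons -0.04 (adjusted p = 0.168). Markers of the remaining cell types had mean shifts of 0.09 for oligodendrocytes, 0.04 for radial glia, 0.20 for microglia, 0.05 for endothelium and -0.09 for meningeal fibroblasts and pericytes (adjusted p between 0.308 and 0.629). In each of the lists that passed 0 members passed over all genes or adjusted over the list alone.

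With limma 0 of 18241 features passed at 24 h (smallest adjusted p 1.00), and 156 had an unadjusted p under 0.05, 101 higher and 55 lower. Values separated the groups for 534 features (2.93%, against 10% by chance). The genes with the smallest unadjusted p, none past the threshold, were Ankrd37, Prss30 (0.74, SE 0.24), the orphan receptor Gpr146 (0.63, SE 0.20), the kinase Map3k11 (0.49, SE 0.15) and the retinoid X receptor Rxra (0.38, SE 0.11). Lower means were found for Bcl2l15 (-0.77, SE 0.19), Atf7 (-0.65, SE 0.21), the centrosomal gene Cep43 (-0.59, SE 0.22, and -0.30 without untreated replicate 2), Tox (-0.36, SE 0.13) and Zfp667 (-0.34, SE 0.10). For Atf7 and Cep43 only 2 of the 3 treated values lay below all untreated ones. With the slide as a block the shifts were 0.15 for the HIF list (adjusted p = 6.54e-06), -0.11 for the channel list (adjusted p = 6.54e-06), 0.14 for astrocyte markers (adjusted p = 4.97e-04) and 0.09 for ribosomal genes (adjusted p = 0.00882). They were -0.04 for glutamate receptor genes (adjusted p = 0.00501), -0.08 for presynaptic genes (adjusted p = 0.00255) and -0.03 for cell cycle genes (adjusted p = 0.00501). Within slide 1, where the 1 sample of 24 h is assumed to vary like the other groups, the HIF shift was 0.19 (adjusted p = 0.137), the channel shift -0.04 (adjusted p = 0.166) and the astrocyte shift 0.15 (adjusted p = 0.584). The ribosomal shift was 0.19 (adjusted p = 0.00698) there and the presynaptic shift -0.05 (adjusted p = 0.137). There the glutamate receptor mean was 0.04 (adjusted p = 0.252) and the cell cycle mean 0.08 (adjusted p = 0.724), both positive while the test pointed down. Within slide 2 the values in the order of the block were 0.14 (adjusted p = 1.88e-04), -0.14 (adjusted p = 1.52e-05), 0.12 (adjusted p = 0.0327), 0.07 (adjusted p = 0.0374), -0.06 (adjusted p = 0.0160), -0.04 (adjusted p = 0.219) and -0.12 (adjusted p = 1.93e-06). Without 24 h replicate 2 the channel shift was -0.07 (adjusted p = 0.0666), the cell cycle shift 0.00 (adjusted p = 0.494), the presynaptic shift -0.06 (adjusted p = 0.226) and the astrocyte shift 0.09 (adjusted p = 0.0821). Without untreated replicate 3 the glutamate receptor shift was -0.00 (adjusted p = 0.552), the presynaptic shift -0.01 (adjusted p = 0.573), the astrocyte shift 0.09 (adjusted p = 0.552) and the ribosomal shift 0.07 (adjusted p = 0.573). Under quantile normalization the ribosomal shift was 0.01 with the test pointing down (adjusted p = 0.927). With normexp background correction the channel shift was -0.04 (adjusted p = 3.11e-04), the presynaptic shift -0.02 (adjusted p = 0.00169), the cell cycle shift -0.02 (adjusted p = 5.37e-04) and the glutamate receptor mean 0.01 with the test pointing down (adjusted p = 0.0298), and the ribosomal shift of 0.08 (adjusted p = 0.783) and the astrocyte shift of 0.13 (adjusted p = 0.104) did not pass.

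**Figure D2:**
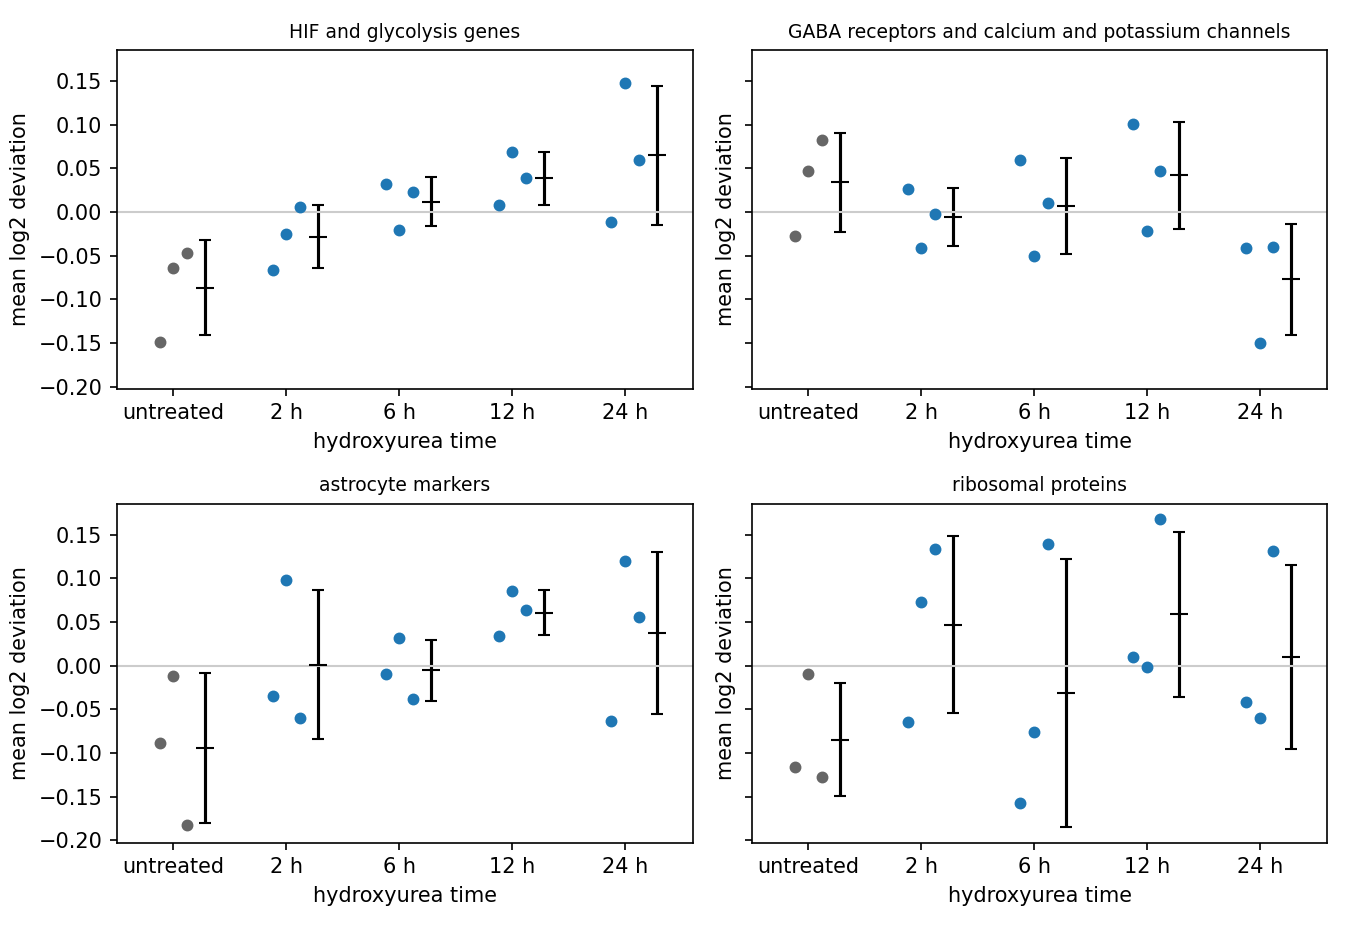
Mean log2 deviation of the members of 4 gene lists from their mean over all samples, for each of the 15 samples (points) by hydroxyurea time, with group means and SD (bars, n = 3). HIF and glycolysis genes lay above all 3 untreated samples in 11 of 12 treated samples, and astrocyte markers in 8 of 12.

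The mean of the 4 times addresses what the treated cultures shared. Ankrd37, a gene that HIF induces, was higher in all 12 treated samples than in any untreated sample, at -2.43 ± 0.21 (SD, n = 12) against -3.13 ± 0.30 (SD, n = 3) on the normalised log2 scale (exact permutation p = 0.00220, the smallest that 455 splits can give). The margin was thin: the lowest treated value was -2.87 (2 h replicate 3) and the highest untreated value -2.88 (untreated replicate 1, averaged over 2 arrays). By the within-slide differences, the first of these 2 arrays alone lay slightly above that treated value. The full separation, and with it the smallest exact p, thus rests on the average and does not hold for the first array alone. The gene was singled out after its values were seen. Its log2 difference of 0.70 (SE 0.15), 1.62-fold, did not pass over all genes with limma (unadjusted p = 5.36e-04, adjusted p = 1.00). It was the 1 list member that passed adjusted over the list alone (adjusted p = 0.0177). With the slide as a block the difference was 0.70 (limma adjusted p = 0.284), and it was 0.69 within slide 1 and 0.55 within slide 2. At 2, 6, 12 and 24 h it was 0.66, 0.63, 0.68 and 0.79 within slide 1 and 0.32, 0.51, 0.72 and 0.66 within slide 2.

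**Figure D3:**
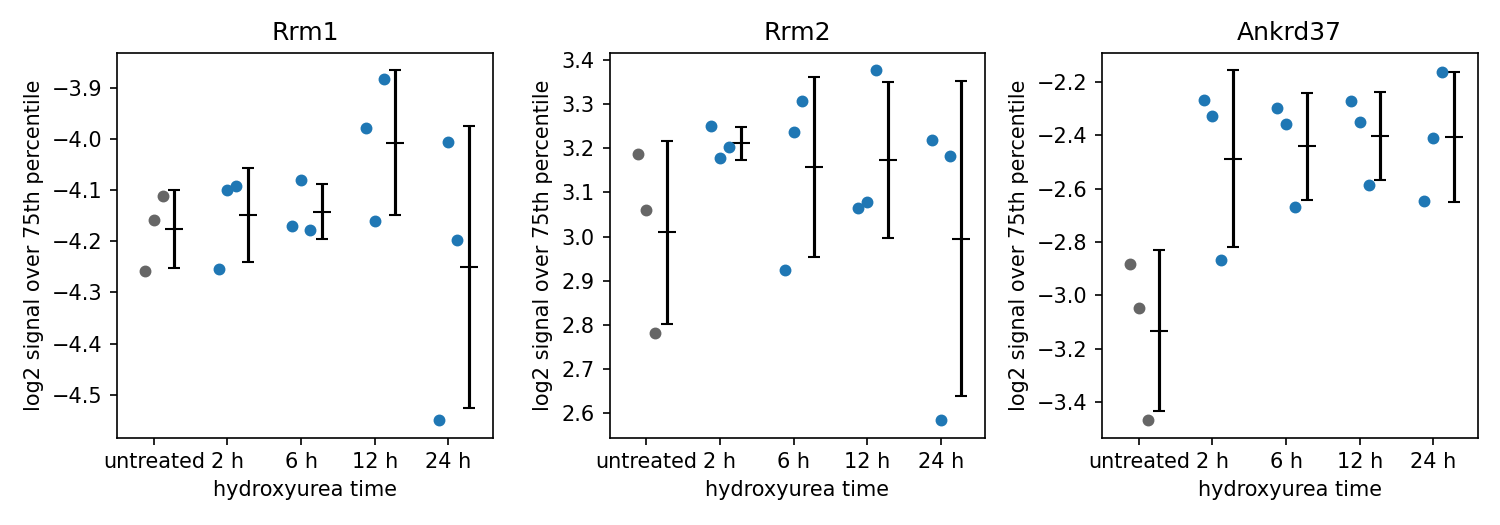
Normalised log2 signal (over the 75th percentile of the array) of Rrm1, Rrm2 and Ankrd37 in each of the 15 samples (points) by hydroxyurea time, with group means and SD (bars, n = 3). The 12 treated values of Ankrd37 lie above the 3 untreated values, with the closest at -2.87 and -2.88, while those of Rrm1 and Rrm2 overlap them. Untreated replicate 1 is shown as the average of its 2 arrays, and its first array alone would not be separated for Ankrd37.

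Over the 4 times HIF and glycolysis genes were higher, 27 of 33, with a mean shift of 0.11 (limma's camera, adjusted p = 1.97e-04; adjusted p = 0.134 with an estimated correlation). Astrocyte markers were higher, 17 of 20, with a mean shift of 0.12 (adjusted p = 2.49e-04; adjusted p = 0.134 with an estimated correlation), and ribosomal protein genes, 35 of 41, with a mean shift of 0.11 (adjusted p = 1.43e-06; adjusted p = 0.845 with an estimated correlation). Aldoc stood at 0.45 (SE 0.14), Pgk1 at 0.66 (SE 0.27), Slc1a2 at 0.33 (SE 0.14) and Rpl13 at 0.16 (SE 0.11). Per sample, the mean deviation of the HIF list was above all untreated samples in 11 of 12 treated samples (exact permutation p = 0.00879, adjusted over the 36 lists 0.316). That of astrocyte markers was so in 8 of 12 (exact permutation p = 0.0176, adjusted 0.316) and that of ribosomal genes in 7 of 12 (exact permutation p = 0.132, adjusted 0.791). Other genes with the smallest unadjusted p, none past the threshold, were Plaur (0.58, SE 0.18), Aifm2 (0.81, SE 0.23) and the prelamin-binding factor Narf (1.17, SE 0.36). On the lower side were Zc3h12b (-0.83, SE 0.24), Cd55 (-0.47, SE 0.14), Atf7 (-0.51, SE 0.17, and -0.32 without untreated replicate 3), Elapor2 (-0.31, SE 0.12) and Tnfaip6 (-0.28, SE 0.11). Second probes gave 0.03 for Aifm2, 0.22 for Narf, 0.08 for Cd55 and 0.35 for Plaur. Those of Cd55 and Plaur were well above background in 0 samples. Without untreated replicate 1 the differences of Aifm2 and Narf were 0.33 and 0.37. Normexp background correction turned the sign of 16 of the 29 negative and 0 of the 33 positive values of named genes over all comparisons.

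With limma 0 of 18241 features passed in the mean of the 4 times (smallest adjusted p 1.00), and 306 had an unadjusted p under 0.05, 257 higher and 49 lower. In 11 features all 12 treated values lay on 1 side of the untreated values, where chance gives 80.2. With the slide as a block the HIF, astrocyte and ribosomal shifts were 0.11, 0.12 and 0.11 (adjusted p = 1.03e-04, 1.93e-04 and 3.37e-06). Within slide 1 they were 0.14, 0.13 and 0.07 (adjusted p = 0.402, 0.820 and 0.834), and within slide 2 they were 0.11, 0.09 and 0.20 (adjusted p = 0.00570, 0.137 and 1.87e-14), where times with 1 sample on a slide are assumed to vary like the other groups. Without untreated replicate 3 the astrocyte shift was 0.07 (adjusted p = 0.509) and the ribosomal shift 0.08 (adjusted p = 0.179), and after quantile normalization the ribosomal shift was 0.02 (adjusted p = 0.661).

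**Figure D4:**
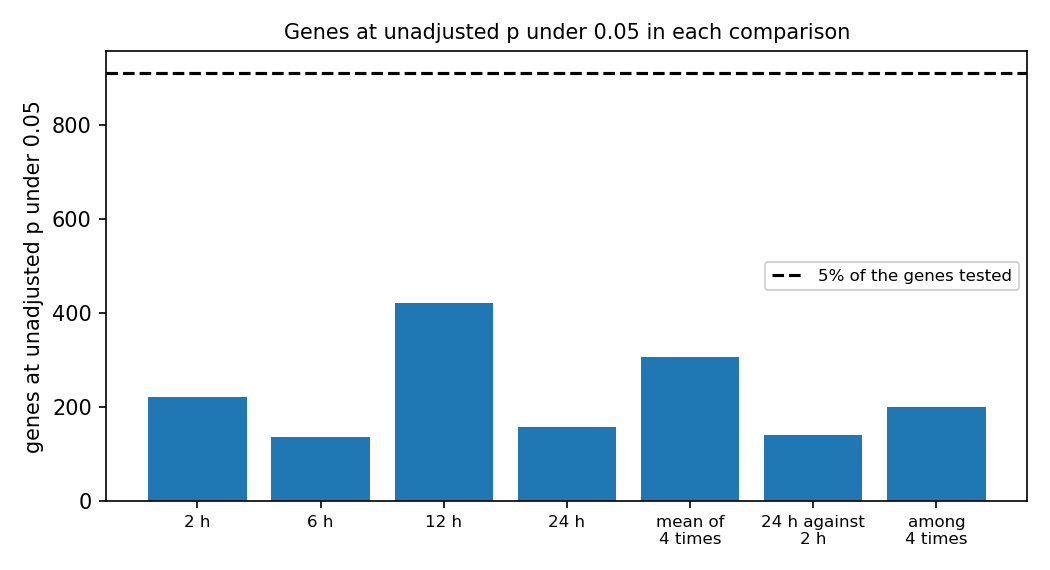
Number of features at an unadjusted p under 0.05 in each of the 7 comparisons (bars), with the number expected by chance (dashed line, 912 of 18241). The highest bar is 12 h against untreated with 422 features.

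None of the lists tied to the known actions of hydroxyurea passed in the mean of the 4 times. Genes of ribonucleotide reductase and deoxynucleotide supply had a mean shift of 0.02, p53 targets 0.06, replication checkpoint and DNA repair genes -0.02, NRF2 and antioxidant genes 0.03, globin and erythroid genes 0.04, iron handling genes -0.01 and genes of nitric oxide and cyclic GMP signalling -0.01 (limma's camera, adjusted p between 0.283 and 0.753). Of 29 measured p53 targets 22 were higher, with Bax at 0.19 (SE 0.13), Cdkn1a at 0.15 (SE 0.15) and Gadd45a at -0.14 (SE 0.09). Cell cycle genes had a mean of 0.01 and a median of -0.02 with the test pointing down (adjusted p = 0.477). Among neuronal groups the shifts were -0.03 for glutamate receptors and the postsynaptic density (adjusted p = 0.0546) and -0.04 for GABA receptors and channels (adjusted p = 0.0584). They were -0.03 for presynaptic release, -0.02 for neuron markers, -0.04 for GABAergic interneuron markers, -0.01 for neurotrophins and growth factors, 0.02 for immediate early genes and -0.01 for Alzheimer disease and amyloid genes (adjusted p between 0.253 and 0.984).

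Stress and metabolic groups did not pass either. Their mean shifts were 0.03 for the integrated stress response, -0.02 for endoplasmic reticulum chaperones, 0.04 for the respiratory chain, and 0.06 for lysosome and autophagy (limma's camera, adjusted p between 0.305 and 0.622). They were 0.03 for interferon-stimulated genes, -0.00 for the circadian clock, 0.04 for glucocorticoid and thyroid responsive genes and 0.05 for Wnt and Notch genes (adjusted p between 0.289 and 0.948). For 4 groups the mean and the median differed in sign: heat shock proteins (0.01 and -0.01), cholesterol synthesis (0.01 and -0.00, test down), apoptosis regulators (0.01 and -0.01, test down) and inflammatory genes (0.00 and -0.01), with adjusted p between 0.891 and 0.984. Markers of other cell types had mean shifts of 0.06 for radial glia, 0.03 for oligodendrocytes, 0.15 for microglia and -0.07 for meningeal fibroblasts and pericytes (adjusted p between 0.371 and 0.753), and those of endothelium had a mean of -0.01 and a median of 0.00 (adjusted p = 0.896).

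Between 24 h and 2 h, the comparison that leaves the untreated group out, HIF and glycolysis genes were higher at 24 h and channel and cell cycle genes lower. Of 33 HIF and glycolysis genes 27 were higher, with a mean shift of 0.09 (limma's camera, adjusted p = 0.009997; adjusted p = 0.430 with an estimated correlation), led by the lactate transporter Slc16a3 (0.55, SE 0.17) and the histone demethylase Kdm3a (0.41, SE 0.21). Of 32 receptor and channel genes 24 were lower, with a mean shift of -0.07 (adjusted p = 0.0147; adjusted p = 0.430 with an estimated correlation), with Kcnd2 at -0.21 (SE 0.10) and Kcnj6 at -0.28 (SE 0.15). Of 43 cell cycle genes 31 were lower, with a mean shift of -0.05 (adjusted p = 0.0148; adjusted p = 0.477 with an estimated correlation), with Tpx2 at -0.29 (SE 0.12) and Birc5 at -0.23 (SE 0.14). In these lists 0 members passed over all genes or adjusted over the list alone. Rrm1 differed by -0.10 (SE 0.13) and Rrm2 by -0.22 (SE 0.17). The list test of this comparison was chosen after the data were seen.

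With limma 0 of 18241 features differed between 24 h and 2 h (140 at an unadjusted p under 0.05, 88 higher and 52 lower), and 0 differed among the 4 times by the F test (200 at an unadjusted p under 0.05). With the slide as a block the adjusted p of the HIF, channel and cell cycle lists was 0.0203, 0.00873 and 0.0227. Within slide 1 the shifts were 0.10, -0.03 and 0.01 (adjusted p = 0.173, 0.140 and 0.627), and within slide 2 they were 0.06, -0.09 and -0.05 (adjusted p = 0.546 each), where the 1 sample of 24 h and the 1 sample of 2 h, respectively, are assumed to vary like the other groups. Without 24 h replicate 2 the shifts were 0.05, -0.03 and -0.02 (adjusted p = 0.186, 0.495 and 0.442), and without 2 h replicate 1 they were 0.07, -0.06 and -0.02 (adjusted p = 0.196, 0.196 and 0.774).

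No gene was called at any time, so 0 genes were shared between times with limma, and 121 features had an unadjusted p under 0.05 at more than 1 time. The log2 differences from untreated correlated across features between times by 0.412 to 0.656 (Pearson's r; features are not independent replicates). Simulated unchanged groups against 3 shared untreated samples gave 0.50. Pairs without 12 h lay above that (2 and 6 h 0.602, 2 and 24 h 0.656, 6 and 24 h 0.557) and pairs with 12 h below it (0.412 to 0.432). The covariances were 0.0155 to 0.0207, below the simulated 0.0256 to 0.0257, and the untreated samples were too few to be split.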

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

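Of the tests in this part, the list test of 24 h against 2 h, the test of a lower share of neurons and the count without the 2 arrays with the poorest replicate spots were chosen only after the results were seen.

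Between 24 h and 2 h of treatment 3 gene lists differed by a test of that difference itself. HIF and glycolysis genes were higher at 24 h by 0.0933 on the log2 scale (limma's camera, adjusted p = 0.009997; adjusted p = 0.430 with an estimated correlation). GABA receptor and channel genes were lower (-0.0712, adjusted p = 0.0147; adjusted p = 0.430 with an estimated correlation). Cell cycle genes were lower (-0.0530, adjusted p = 0.0148; adjusted p = 0.477 with an estimated correlation), and without 24 h replicate 2 none of the 3 passed, at 0.0521, -0.0346 and -0.0177 (adjusted p = 0.186, 0.495 and 0.442). Of the 10 splits of these 6 samples 4, the real one included, gave as many lists, too few splits for a share under 0.05, with 3 lists in the real split and at most 9 in another.

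HIF and glycolysis genes were higher and receptor and channel genes lower at 24 h by camera and not by fry (adjusted p = 0.192 and 0.477), in a group whose replicate 2 stands apart from the other two by a median of 0.25 per feature. Without that sample 72.7% of the HIF shift and 66.9% of the channel shift were left, and with the slide in the model at least 96.7%. Within slide 1, which holds 1 sample of 24 h, the HIF shift was 0.19 and the channel shift -0.04, so the slide stays open for the channel list. Without the 2 poorest arrays the 7 lists called at 24 h were all still called. That check could hardly fail, because 1 of these arrays is of 12 h and the other belongs to an averaged pair. Among 10000 random lists matched on mean signal the HIF median lay at percentile 100 and the channel median at percentile 0. These 2 lists were already called at 24 h in the same data, and random genes do not vary together as list members may. The percentiles therefore speak only to signal level and are no further support for the shifts. Replicate 2 and signal level thus do not account for the whole of either shift, nor the slide for that of the HIF list. The channel call was still lost without 24 h replicate 2 (limma's camera, adjusted p = 0.0666). Of the 10 splits of the 24 h and untreated samples 4, the real one included, gave as many lists, too few splits for a share under 0.05. The real split gave 7 lists and another at most 14. A lower share of neurons among the cells stays open: 18 of 20 astrocyte markers were higher and 13 of 19 neuron markers lower (0.13 and -0.04), and between the markers of 2 of the 6 other cell types the largest t of a difference was 1.34, too small to exclude it. Time spent in medium without antioxidants, not tested because the untreated group is not known to be matched in time, and a response of the neurons to 24 h of hydroxyurea stay open as hypotheses.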

How the results depend on the processing

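The alternatives without the 2 poorest arrays, with exchanged 24 h numbers, and the list test of 24 h against 2 h were chosen after seeing the data; the others were fixed before the data were examined. With limma, 0 genes were called under nearly all of the 38 or 39 settings run for each comparison. Quantile normalization called 1 unnamed probe at 12 h (A_43_P16262, -1.76, adjusted p = 0.0238). Within slide 1 there were 4 features at 12 h: Adrb1 3.77, Tvp23a 2.73 and the unnamed probes A_42_P674192 2.47 and A_64_P391863 2.76, against 1.29, 0.95, 1.03 and 0.76 over both slides. There 12 h has 1 sample, which is assumed to vary like the other groups. The last call was Ankrd37 in the mean of the 4 times with the exchanged numbers. All 6 were chosen after their values were seen. At an unadjusted p under 0.05 the counts were 220, 136, 422 and 156 genes at 2, 6, 12 and 24 h, 306 in the mean, 140 for 24 h against 2 h, 200 among the times and 121 shared by times; this threshold makes no correction for the number of genes. All values of Ankrd37 stayed positive in these settings, with adjusted p from 0.0200 to 1.00 in the mean of the 4 times.

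The counts of lists, 1, 2, 3 and 7 at 2, 6, 12 and 24 h, 3 in the mean and 3 for 24 h against 2 h, moved more, and the cause was not tested unless named. With an estimated correlation they were 0, 0, 0, 2, 0 and 0, because members of a list are then allowed to vary together, and with fry 0 throughout. Quantile normalization gave 0 at 2 h, 1 at 6 h and 0 at 12 h. Normexp, under which the median of all genes at 12 h was 0.10 against 0.02 in the scaling used, gave 0 at 6 h, 1 at 12 h (down), 0 in the mean and 5 for 24 h against 2 h (1 up, 4 down). The Z-score gave 4 at 2 h (3 up, 1 down), 5 at 6 h (all up) and 5 in the mean (4 up, 1 down), and the deposited scores 4 (3 up, 1 down), 5 (all up) and 6 (4 up, 2 down). Array weights gave 3 at 2 h and 7 at 12 h, and the trended robust fit 2 at 2 h. Testing every probe gave 2 at 2 h, 1 at 6 h and 6 in the mean, and the mean of a gene's probes 2, 1 and 5. Calls ended by normexp were HIF (adjusted p = 0.147) and astrocyte (0.901) at 6 h, HIF (0.649), ribosomal (0.684) and astrocyte (0.562) at 12 h, ribosomal (0.783) and astrocyte (0.104) at 24 h, and HIF (0.0830), ribosomal (0.589) and astrocyte (0.238) in the mean. The presynaptic call at 24 h was ended by the Z-score (0.0876) and the deposited scores (0.127). The first array alone ended HIF at 12 h (0.0624) and cell cycle (0.0576) and ribosomal (0.0525) at 24 h, and the filter on every sample ended HIF at 12 h (0.0534). Array weights ended the astrocyte call at 6 h (0.0642), the cell cycle (0.552) and presynaptic (0.258) calls at 24 h and the cell cycle (0.451) and channel (0.695) calls of 24 h against 2 h. Leaving out the dim filter ended HIF (0.348) and astrocyte (0.493) at 6 h, HIF (0.286) and astrocyte (0.199) at 12 h, ribosomal (0.0925) and astrocyte (0.0690) at 24 h, HIF (0.118) and astrocyte (0.1203) in the mean, and cell cycle (0.247) and channel (0.233) for 24 h against 2 h. Without a filter on dim probes there were 2 at 2 h, 0 at 6 h, 1 at 12 h and 1 for 24 h against 2 h, and with probes well above background in every sample 2 at 2 h and 5 in the mean. The repeat array alone gave 2 at 2 h and 5 in the mean, the first array alone 1 at 6 h, and a fit on only the groups compared 1 at 6 h. Slide 1 alone, with fewer samples, gave 0 at 2 h, 0 at 12 h, 1 at 24 h, 0 in the mean and 1 for 24 h against 2 h. Slide 2 alone gave 2 at 2 h, 4 at 6 h, 1 at 12 h, 11 at 24 h and 6 in the mean. The slide as a block gave 1 at 6 h and 6 for 24 h against 2 h. Without the 2 poorest arrays the counts were 2 at 2 h, 9 at 12 h and 7 in the mean.

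With the replicate number as a replicate block the gene counts stayed at 0 and the lists at 6 h fell to 1. With block and slide together 24 h against 2 h had 5 lists, and with the 24 h numbers exchanged there were 1 list at 6 h and 1 gene in the mean (Ankrd37). The numbers do not meet the rule for pairing: same-numbered samples correlated by a mean of 0.0916 over 30 pairs (-0.417 to 0.419), 19 of them above 0.1, and 11 of 15 samples were closest to their own number, which is a hint from the data and not from the design. After exchanging 24 h replicates 1 and 3 the mean was 0.183, the lowest 0.0137, 24 pairs were above 0.1 and 15 of 15 samples were closest to their own number. Of 12 block fits tried 4 called a gene, each time Ankrd37 with exchanged numbers (adjusted p = 0.0200, 0.0480, 0.0141 and 0.0161). The fit of all 16 arrays with the sample as a random block was not run further, because it gave no estimated correlation for any of 18225 features.

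Leaving out each replicate in turn gave 1 to 8 lists at 2 h, 0 to 4 at 6 h, 0 to 9 at 12 h, 3 to 11 at 24 h, 1 to 9 in the mean and 1 to 6 for 24 h against 2 h. Counts moved by over 1.5 times at 2 h without 2 h replicate 1 (2), 2 h replicate 3 (8) or untreated replicate 1 (3). At 6 h they did so without 6 h replicate 1 (4), untreated replicate 2 (0), and 12 h replicates 1, 2 or 3 or 24 h replicates 1 or 2 (1 each, through the shared spread). At 12 h they did so without 12 h replicate 2 (1), 12 h replicate 3 (9) or untreated replicate 3 (0). At 24 h they did so without 24 h replicate 2 (4), 24 h replicate 3 (4), untreated replicate 2 (11) or untreated replicate 3 (3). In the mean they did so without 12 h replicate 3, 2 h replicate 3 or 6 h replicate 1 (6 each), untreated replicate 1 (9) or untreated replicate 3 (1), and for 24 h against 2 h without 24 h replicate 1 (6) or 24 h replicate 2 (1). Single calls were also lost. The 24 h cell cycle list was lost without untreated replicate 1 (adjusted p = 0.348), and the 12 h HIF list without untreated replicate 2 (0.143) and without 12 h replicate 2 (0.493), where the astrocyte list was lost too (0.391). The 6 h astrocyte list was lost without untreated replicates 2 (0.106) or 3 (0.990), 6 h replicates 1 (0.164) or 2 (0.284), 12 h replicates 1 (0.0539), 2 (0.0555) or 3 (0.0740), or 24 h replicates 1 (0.0600) or 2 (0.0802). For 24 h against 2 h the channel list was lost without 2 h replicate 3 (0.0549) or 24 h replicate 3 (0.148). The 24 h glutamate receptor, presynaptic and ribosomal lists were lost without 24 h replicate 3 (0.119, 0.405 and 0.862). List shifts that moved by over 1.5 times when a replicate was left out were as follows. At 24 h the glutamate receptor shift was -0.0984 and -0.00363 without untreated replicates 1 and 3 and -0.0210 without 24 h replicate 1, and the presynaptic shift -0.115 and -0.00967 without untreated replicates 1 and 3. The cell cycle shift at 24 h was -0.0180 without untreated replicate 1 and 0.000232 and -0.0791 without 24 h replicates 2 and 3, the ribosomal shift 0.0340 without 24 h replicate 3 and the astrocyte shift 0.0873 without untreated replicate 3. Without untreated replicate 3 the astrocyte shift was 0.0449 at 6 h and 0.0736 in the mean, and without 12 h replicate 3 the ribosomal shift at 12 h was 0.0888. For 24 h against 2 h the HIF and channel shifts were 0.0521 and -0.0346 without 24 h replicate 2, and the cell cycle shift was -0.0157 without 2 h replicate 1 and -0.0177 and -0.0969 without 24 h replicates 2 and 3. With array weights the ribosomal shift was 0.0674 at 12 h and 0.0679 in the mean, and at 24 h the astrocyte shift was 0.0678, the glutamate receptor shift -0.0691 and the cell cycle shift -0.00759. For 24 h against 2 h the weights gave -0.0282 for channels and -0.0194 for cell cycle, and normexp -0.0364 for channels. The cell cycle shift at 24 h was -0.0110 with the first array alone and -0.0593 with the repeat array alone. The Z-score and the deposited scores are in units of SD, so their sizes are not compared. At 24 h, without untreated replicate 3, the glutamate receptor, presynaptic, ribosomal and astrocyte lists had adjusted p of 0.552, 0.573, 0.573 and 0.552.

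Values of single genes reversed as follows, none past the threshold on either side. For Rrm1 at 2 h the Z-score gave -0.0138, the first array alone -0.0453, slide 1 -0.0774 and the deposited scores -0.0183. At 6 h these gave -0.0123, -0.0389, -0.0250 and -0.0183, and in the mean -0.00900, -0.0339, -0.0197 and -0.0125, with array weights -0.00781 in the mean. At 24 h Rrm1 was 0.10 with normexp and 0.0153 within slide 2. For Rrm2 slide 1 alone gave -0.0554 at 6 h, -0.0709 at 12 h, 0.0456 at 24 h and -0.000576 in the mean. At 24 h Rrm2 was 0.00449 with the Z-score, 0.12 with array weights, 0.0130 with normexp and 0.00500 with the deposited scores. Leaving out a replicate gave Rrm1 values of -0.0140 (without untreated replicate 1) to 0.0806 (without 2 h replicate 1) at 2 h and -0.00760 (without untreated replicate 1) to 0.0664 (without untreated replicate 3) at 6 h. Without 2 h replicate 3 Rrm1 at 2 h was -0.00119. At 24 h the values of Rrm1 were -0.20 (without 24 h replicate 2) to 0.0744 (without 24 h replicate 1), in the mean -0.00265 (without untreated replicate 1) to 0.0760 (without 24 h replicate 1) and for 24 h against 2 h -0.22 (without 24 h replicate 2) to 0.0471 (without 24 h replicate 1). Rrm2 at 24 h was between -0.13 (without untreated replicate 3) and 0.19 (without 24 h replicate 2), with 0.0743 and 0.0112 without untreated replicates 1 and 2. Normexp turned named values positive. At 2 h these were Akr1b8 0.0140 and Tnfaip6 0.0449, at 6 h Cdc27 0.0335, Nr0b1 0.000745, Paqr5 0.0677 and Zc3h12b 0.0287, at 12 h Cd55 0.14, Ggt1 0.12, Henmt1 0.0232 and Tmod1 0.11, and in the mean Atf7 0.0355, Cd55 0.0879, Tnfaip6 0.10 and Zc3h12b 0.0427. The cause was not tested. Most of these genes are close to background: Akr1b8, Zc3h12b and, at 12 h, Cd55 have only a bound in treated samples.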

Other observations

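In this part, the use of the repeat array alone, itself a setting fixed before, as a test of Ankrd37, the comparison of Ankrd37 with the other HIF genes and all tests of the exchanged 24 h numbers were chosen only after the results were seen, as were the genes named. The label given to the count of labellings below was also settled after that count was seen.

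Single members of lists that did not pass as groups in these comparisons had an unadjusted p under 0.05. The microglial transcription factor gene Spi1 stood at a log2 difference of 2.22 (SE 0.83) at 2 h and 1.62 (SE 0.66) in the mean of the 4 times, the glutathione transferase Gsta4 at 0.51 (SE 0.22) in the mean, and the matricellular gene Ccn1 at 1.31 (SE 0.57) at 6 h. Among synaptic genes the NMDA receptor subunit Grin1 stood at -0.32 (SE 0.14) in the mean of the 4 times and -0.43 (SE 0.17) at 12 h, and the kinase Camk2b at -0.52 (SE 0.23) at 12 h. None passed with limma over all genes or adjusted over the list alone. Over all features 1.21%, 0.75%, 2.31% and 1.68% had an unadjusted p under 0.05 at 2, 6 and 12 h and in the mean. Each share is below that of the 912 features expected by chance, so this level alone singles out no member.

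Ankrd37 was higher in all 12 treated samples, by a mean of 0.70 on the log2 scale, with the closest treated and untreated values at -2.87 and -2.88. Its mean difference was 0.70 with the repeat array alone in place of the pair of untreated replicate 1. Of the spots of its probe 10 of 10 showed a difference of at least 0.35, and the smaller of the within-slide differences was 0.55. The poor first array, a few bad spots or the slide thus do not account for the mean difference. The full separation holds for the average of the 2 arrays of untreated replicate 1 and not for its first array alone. The other 32 HIF and glycolysis genes had a median of 0.0631 (0.13 at 2 standard errors above), below the 25% of the Ankrd37 difference (0.17) asked of a general rise. Of them 26 were higher, by at most 0.66. The list mixes HIF targets with genes of glycolysis, so its median shows only that the list as a whole rose less than Ankrd37. A rise shared with some HIF targets stays open. Selection among all genes stays undecided. The untreated sample was relabelled within each number in 100 labellings. In 3 of them, the real one included, a gene had as small a limma p as the block with exchanged 24 h numbers (1.10e-06, smallest other 3.15e-07). Over the 10 fits scored per labelling 4 of 100 did so, and the 95% interval of this share, 1.1% to 9.93%, spans the 5% of the prediction. Block fits without 12 h replicate 3, of which 1 also called Ankrd37, were not scored, so the count does not cover every fit tried. A response of this HIF target to hydroxyurea, or to the change of medium, may underlie the difference as a hypothesis; the 0.70 cannot separate them.

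The value table pairs the columns of 24 h replicates 1 and 3 with each other's scanner file. If the scanner files were exchanged, the deviations of the 24 h samples may follow those of same-numbered samples better after exchange, and they did: their mean correlation was 0.188 exchanged and -0.0403 as labelled (highest of the other 4 assignments 0.0256). With the slide taken out of the values this turned, 0.0591 exchanged and 0.183 as labelled, but outside 24 h all samples of number 3 lie on slide 2, so taking out the slide also takes out part of the number. In 849 features that set number 3 apart on all arrays outside 24 h, the file of 24 h replicate 1 was nearer number 3 in 63.8% and that of replicate 3 in 14.3%. This is on the side of exchanged files but short of the 80% asked, a limit written after other results were seen. No held-out sample of number 3 reached that limit, so it could hardly be met and decides nothing. Held-out samples of number 3 reached 42.2% to 71.5%, and those of numbers 1 and 2 outside 24 h 7.0% to 22.2%. Of the number 2 samples on slide 2, 24 h replicate 2 gave 44.3% and 12 h replicate 2 gave 20.7%, so the slide may still enter. Whether the scanner files or only the value-table columns were exchanged therefore stays open, and while differences between group means do not depend on it, fits that use the replicate numbers do.

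For the counts of genes, other splits of the same samples were tested at an unadjusted p under 0.05, and each number of splits includes the real one. The 10 splits of each pair of groups are too few for a share under 0.05: at 2 h 8 of 10 splits gave as many genes (220 in the real split, at most 1062 in another), at 6 h 9 (136, 614), at 12 h 10 (422, 1610), at 24 h 9 (156, 2362) and for 24 h against 2 h 10 (140, 1477). For the mean of the 4 times 80 of 100 splits gave as many (306, 3539), and for the difference among times 100 of 100 (200, 2190), so chance cannot be excluded for either. Some splits called several times the real number of genes, but at 6 h even the largest count (614) was under the 912 expected by chance. Same-numbered samples did vary together to a degree: 11 of 15 samples were closest to their own number as labelled, and 15 of 15 after the exchange at 24 h. The 912 and the 10% assume independent samples, so counts below them do not show that no gene changed. Whether this structure underlies such splits or the low counts was not tested. For the lists, 8 of 10 splits gave as many at 2 h (1 in the real split, at most 6 in another), 9 of 10 at 6 h (2, 9) and 5 of 10 at 12 h (3, 6), again too few splits for a share under 0.05, and 62 of 100 did for the mean of the 4 times (3, 10), where chance cannot be excluded.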
